A study of Mus musculus with 3 samples.

How the data were processed

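Libraries were made from fixed thymocytes and sequenced as single-end reads on an Illumina HiSeq instrument, per the labels' protocols. Per the submitters' processing notes, BWA, SAMtools, MACS3 and bedtools were used and the build was mm10. The versions, settings and roles of these tools were not given in the sources used here, nor was whether the input served as the control for both lists. If it did, chance dips of the input would add peaks to both lists at the same places, which was not simulated because reads were not used here.

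The authors deposited 1 peak list for each antibody, with 1 row per peak and no header, in the 10-column layout that MACS writes. Both lists hold the peaks of 1 library, and no pooling is recorded. In each deposited list the values are a score, which equals 10 times the −log10 q rounded down, the fold enrichment at the summit as a ratio, the −log10 p-value and the −log10 q-value at the summit, and the position of the summit. The lowest −log10 q was 1.6 for sc816 and 1.44 for sc13062. Peak names carry running numbers with gaps. Of 1177 numbers up to the last, 605 (51.4%) are missing from the sc816 list, and of 11634, 661 (5.68%) are missing from the sc13062 list, so peaks were removed after calling by a rule not given in the sources used here. The peak names of the sc816 list carry the number 815, while the label names the antibody sc816. The antibody is named here as in the label, and the difference was left unsettled. Signal tracks, read counts and the input library were not analysed here. The depth of each library is therefore unknown, and the number of peaks per list cannot be set against it.

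Genes were taken from an NCBI RefSeq table of the assembly GRCm38, which has the coordinates of mm10. It gives the start and end of each gene but neither strand nor exons. The design called for the transcription start of each gene, and the table does not tell which end that is, so both ends were used throughout. The 21631 protein-coding genes on chromosomes 1 to 19 and X entered the tests. No genome sequence was used here, so the planned searches for androgen response elements, their spacing and their relation to peak strength were not run. Locations of all peaks are 1-based.

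Peaks were called shared when they overlapped by at least 1 bp. The number of shared sc816 peaks was compared with 1000 random placements of those peaks on their own chromosome within the span of the sc13062 peaks (one-sided permutation test). A second version placed peaks within 1 kb of a gene end and all others separately. Medians of log2 fold enrichment were compared within each list by permutation tests with 100000 resamples (two-sided). Shares carry exact Clopper-Pearson 95% intervals, which cover counting over peaks or genes alone. Location was compared with 10 random positions per peak on the same chromosome, and between lists, by two-sided Fisher exact tests. For 15 gene lists fixed before the data were examined, members with a summit within 10 kb of a gene end were compared with all other protein-coding genes by two-sided Fisher exact tests, adjusted by the Benjamini-Hochberg method over 30 tests and called at 0.05. Names were matched through symbols and synonyms. In the negative-regulator list 2 names, in the transcription factor list 1 and in the erythroid list 1 were not matched or matched an unrelated gene and were left out, and the histone names, 32 as written, came to 15 genes under current symbols.

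Named genes followed a rule fixed before the data were examined. It took the nearest protein-coding gene of the 10 peaks with the largest fold enrichment per antibody, the 10 shared peaks with the smallest worse rank over both lists, up to 15 fixed-list genes with a summit within 10 kb, those in both lists first and then by sc13062 fold enrichment, and Ar, Fkbp5, Zbtb16, Tsc22d3, Per1, Ptpn22 and Ptpn1 whatever their values. Alternatives fixed in advance were stricter −log10 q and fold enrichment thresholds, other definitions of a shared peak, a shortened sc13062 list, removal of unplaced sequences and wide peaks, −log10 q in place of fold enrichment, and other distances to genes.

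The procedures were tested on simulated lists of 500 and 10000 peaks. Without shared sites or gene preference the overlap test called 1 of 20 simulations. With a preference for gene ends in both lists but no shared sites, the unstratified test called 20 of 20, with a median ratio of 11.1, and the stratified test 1 of 20. When that preference was narrowed to 400 bp the stratified test called 16 of 20, with a median ratio of 1.87, so a stratified ratio near 2 has no weight. The simulated preference was spread evenly over the ends of all protein-coding genes. A preference of both lists for the ends of the same genes was not simulated, so the ratio it would give is unknown. With 100 planted shared sites it called 20 of 20. Of lists with peaks planted at 80% of their genes, 99 of 100 were called, and of unchanged lists 5 of 200. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.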

Results

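Chromatin immunoprecipitation followed by sequencing was carried out on mouse thymocytes, the developing T cells of the thymus, with antibodies against the androgen receptor, a steroid-activated transcription factor encoded by the X-linked gene Ar. The cells had been exposed to 100 nM dihydrotestosterone, its natural ligand, dissolved in DMSO, for 4 h. The series holds 3 samples: 1 library made with the antibody sc816, 1 library made with the antibody sc13062 and 1 input library, which was not analysed here. No thymocytes without dihydrotestosterone were among the samples, so no comparison concerns the response to the hormone. Each antibody had 1 library, so no value has a replicate error. Intervals and p-values below describe the spread over peaks or genes within these lists, and neighbouring peaks and genes are not independent. Numbers of reads per library were not given in the sources used here, so the depth is unknown. The title of the series places the work in androgen regulation of T cells and sex bias in autoimmunity. The questions addressed by the files are where each antibody enriched DNA, whether both antibodies enriched the same sites, and which genes lie near those sites.

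The sc13062 list was far longer than the sc816 list. It held 10973 peaks covering 2829453 bp, against 572 peaks covering 127230 bp for sc816. The peaks were narrow in both, with a median width of 214 bp for sc13062 and 145 bp for sc816. The fold enrichment, the authors' own value for each peak, had a median of 7.04 and a maximum of 70.5 in the sc13062 list, and a median of 6.41 and a maximum of 33.2 in the sc816 list. On chromosomes 1 to 19 and X lay 10932 of the sc13062 peaks and 519 of the sc816 peaks. A further 32 sc13062 peaks and 37 sc816 peaks lay on the unplaced sequence JH584304. At a −log10 q of at least 10 the lists fell to 3810 and 139 peaks, and at 5 or more the sc816 list fell to 362.

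The highest fold enrichment, 70.5, in the sc13062 list was at the AP-1 transcription factor gene Junb (chromosome 8, 84978463 to 84979094, mm10), with the summit 48 bp from a gene end. It was followed by H3f3b, which encodes the replacement histone H3.3 (69.4), the antiproliferative gene Btg1 (67.0), the splicing factor genes Srsf2 (66.3) and Srsf7 (65.0), Tex14 (65.4), Rgcc (62.5), Rdm1 (61.7), the antiproliferative gene Tob1 (61.3) and Polr2a (61.2), which encodes the largest subunit of RNA polymerase II. Each of these 10 peaks is named by its nearest protein-coding gene end. In 6 of them the summit lay within 1 kb of that end, in 9 it lay inside a gene, and none overlapped an sc816 peak. The Srsf2 summit lay inside both Srsf2 and Mfsd11, and the Tex14 summit lay 57342 bp from the nearer end of that gene.

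The strongest sc816 peaks lay elsewhere. The highest fold enrichment, 33.2, was inside Cdh17, a cadherin gene (chromosome 4, 11794374 to 11794696), 23391 bp from the nearer gene end. Next came peaks inside Dmwd (22.8) and Arhgap26 (22.1), then peaks between genes with Efcab11 (21.0), Gadd45g (20.2) and Nav2 (19.98) as their nearest genes. The Gadd45g peak was 178094 bp from that gene. The remaining 4 were nearest to Uaca (17.3), Anapc16 (16.6), Hmg20a (15.3) and the matrix metalloproteinase gene Mmp9 (14.7). Of these 10 peaks, 5 had their summit inside a gene, 0 lay within 1 kb of a gene end, and 2, at Uaca and Anapc16, overlapped an sc13062 peak.

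Both antibodies enriched a common set of sites more often than random placement gave, yet most peaks of either list were found with that antibody alone. Of the 572 sc816 peaks, 207 (36.2%, exact 95% interval 32.2 to 40.3%) overlapped an sc13062 peak by at least 1 bp, and 201 of the 10973 sc13062 peaks (1.83%, 1.59 to 2.10%) overlapped an sc816 peak. Random placement of the sc816 peaks on their own chromosome gave 35.1 ± 3.08 shared peaks (SD over 1000 placements), so the observed number was 5.89 times random (one-sided permutation p = 0.001, the smallest these placements can give). Most of that random overlap came from short unplaced sequences on which a placed peak had little room. On chromosomes 1 to 19 and X, a restriction chosen after the data were seen, 163 of 519 sc816 peaks were shared (31.4%, exact interval 27.4 to 35.6%), against 0.998 ± 0.979 at random, 163 times more. Placing peaks within 1 kb of a gene end and all other peaks separately gave 38.2 ± 3.67 random overlaps over all sequences, a ratio of 5.42, and 4.16 ± 1.96 on chromosomes 1 to 19 and X, a ratio of 39.1 (permutation p = 0.001 for each, again the smallest possible). The separate placement draws on the ends of all protein-coding genes, so a preference of both lists for the ends of the same genes is not taken out. Cutting the sc13062 list to its 572 strongest peaks left 2.10% of sc816 peaks shared.

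The 10 shared sites with the smallest worse rank by fold enrichment over both lists are named here by their nearest gene. Their ranks ran from 25 (Calm1) to 352 (Prps1) of 10973 with sc13062. With sc816 they ran from 8 (Anapc16) to 471 (H3c6) of 572, so several were among the weaker sc816 peaks. Near Anapc16, a gene of the anaphase-promoting complex, the summits lay 7 bp apart (chromosome 10, 59974265 and 59974272), with fold enrichments of 16.6 with sc816 and 46.2 with sc13062. Inside Ccnd3, which encodes cyclin D3, they lay 17 bp apart (chromosome 17, 47508172 and 47508155), with fold enrichments of 11.6 and 25.2. On the X chromosome a shared site lay 29839 bp from Prps1 (140505979 and 140505977), at 10.7 and 24.5. The other 7 of the 10 were at Raly, Rock1, Rnaset2a, the calmodulin gene Calm1 and the replication-dependent histone genes H3c8, H3c10 and H3c6. Their fold enrichments ranged from 5.29 (H3c6) to 7.80 (Raly) with sc816, and from 27.0 (Rock1) to 53.7 (Calm1) with sc13062. In 6 of the 10 the sc816 summit lay within 1 kb of a gene end.

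Shared peaks were not uniformly stronger than the others. In the sc816 list the median fold enrichment was 6.41 for both the 207 shared and the 365 other peaks (two-sided permutation p = 1). In the sc13062 list it was 6.50 for the 201 shared and 7.04 for the 10772 other peaks, a log2 difference of -0.12 (two-sided permutation p = 0.00751). These values include the peaks on the unplaced sequence JH584304, which had a median fold enrichment of 3.18 with sc816 and 3.05 with sc13062. On chromosomes 1 to 19 and X, a restriction chosen after the data were seen, the medians were 6.94 and 6.49 in the sc816 list (log2 difference 0.098, permutation p = 0.0102) and 7.27 and 7.04 in the sc13062 list (0.047, permutation p = 0.488). Ranked by −log10 q over all sequences, shared peaks stood higher in both lists, with medians of 8.24 against 5.45 for sc816 and 10.1 against 7.44 for sc13062 (permutation p = 1e-05 for each, the smallest the resamples can give).

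The lists also differed in where their peaks lay. Of the sc13062 peaks on chromosomes 1 to 19 and X, 64.7% (exact 95% interval 63.8 to 65.6%) had their summit within 1 kb of an end of a protein-coding gene, 24.3% lay elsewhere inside a gene and 11.1% lay between genes. Random positions on the same chromosomes gave 3.36%, 39.9% and 56.8%. The gene-end share was 19.2 times random, with a two-sided Fisher exact p too small for the computation to hold. Of the sc816 peaks, 16.2% (13.1 to 19.6%) lay within 1 kb of a gene end, 38.9% elsewhere inside a gene and 44.9% between genes, against 3.22%, 39.6% and 57.2% at random. Their gene-end share was 5.03 times random (two-sided Fisher exact p = 1.16e-28), while their share inside genes was not distinguishable from random (Fisher exact p = 0.814). The gene-end shares of the lists differed by 48.5 percentage points (two-sided Fisher exact p = 2.6e-109). Exons, introns and untranslated regions were not told apart.

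Shared peaks stood between the lists. Among the sc816 peaks, 38.0% of the 163 shared ones but 6.18% of the 356 others lay within 1 kb of a gene end (two-sided Fisher exact p = 1.6e-18). Among the sc13062 peaks the order was opposite, with 38.8% of the 165 shared and 65.1% of the 10767 others (Fisher exact p = 1.06e-11). In the sc13062 list the share at gene ends rose with peak strength, from 47.1% in the lowest to 80.8% in the highest of 4 equal groups by fold enrichment (Spearman's rho across peaks 0.278, two-sided permutation p = 1e-05, the smallest possible). In the sc816 list it did not follow strength (rho -0.034, permutation p = 0.447), with 13.8% in the highest group and 16.9% in the lowest. These groups were set after the data were seen.

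**Figure D1:**
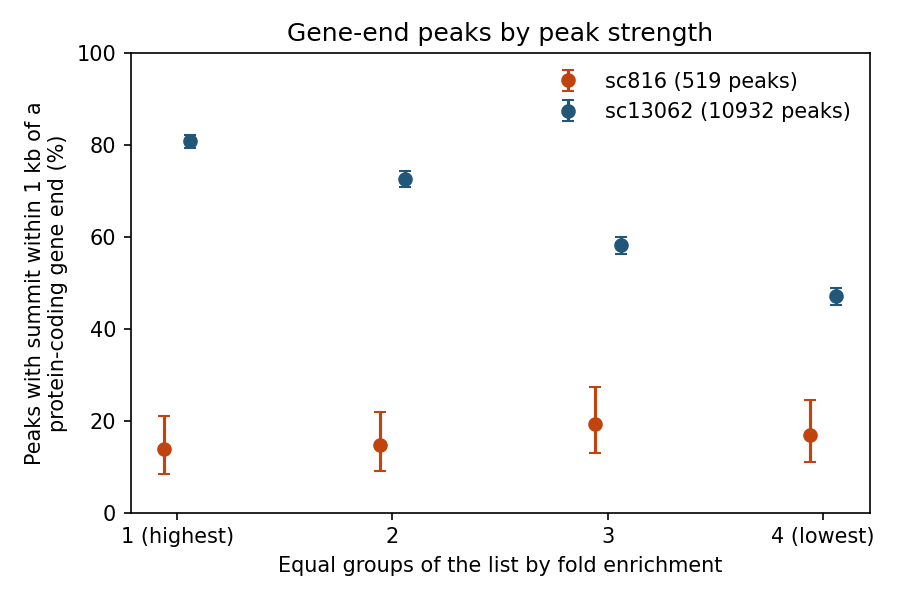
Percent of peaks on chromosomes 1 to 19 and X with a summit within 1 kb of a protein-coding gene end (vertical axis) in each of 4 equal groups of the list by fold enrichment (horizontal axis); points are 1 library per antibody and bars are exact 95% binomial intervals over peaks. The sc13062 share falls from 80.8% to 47.1% from the highest to the lowest group, and the sc816 shares lie between 13.8% and 19.4%.

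Genes of T cell receptor signalling, its negative regulators, thymocyte transcription factors, thymocyte apoptosis and selection, and targets that steroid receptors share lay near peaks of both antibodies more often than other genes did. With sc13062, 8755 of 21631 protein-coding genes (40.5%) had a summit within 10 kb of either gene end. The share was 83.3% for the steroid-receptor list (20 of 24 genes) and 80% for T cell receptor signalling (24 of 30), each with adjusted p = 0.000373 by two-sided Fisher exact tests with Benjamini-Hochberg adjustment over 30 tests. It was 72.7% for the negative regulators (16 of 22, adjusted exact p = 0.0122), 72.4% for the transcription factors (21 of 29, adjusted exact p = 0.00445) and 69.6% for apoptosis and selection (16 of 23, adjusted exact p = 0.0136). Classical androgen targets, taken mostly from prostate, had a peak in 15 of 26 cases (57.7%, exact interval 36.9 to 76.6%), which did not pass the adjustment (adjusted exact p = 0.231). Androgen targets mostly of the male reproductive tract lay below other genes, with 1 of 21 (4.76%, adjusted exact p = 0.00427). So did a control list, with 2 of 20 (10.0%, adjusted exact p = 0.0136), although it lost the call at 50 kb (7 of 20, adjusted exact p = 0.1). This control list, called liver and neuron genes here, also holds pancreas, muscle and glial genes. The 3 genes with a peak within 10 kb in these lists, named after their values were seen, were Msmb, Gfap and Mbp.

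Few genes lay near an sc816 peak, 296 of 21631 (1.37%), yet the same 5 lists passed the adjustment. They had 4 of 30 genes for T cell receptor signalling and 4 of 29 for the transcription factors (adjusted exact p = 0.00427 for each), 3 of 22 for the negative regulators and 3 of 23 for apoptosis and selection (adjusted exact p = 0.0122 for each), and 3 of 24 for the steroid-receptor list (adjusted exact p = 0.0124). None of the 26 classical androgen targets had an sc816 peak within 10 kb of a gene end, which allows a share of up to 13.2% by the exact interval. Some of these calls depended on the distance or the threshold. Within 1 kb, the negative regulators (adjusted exact p = 0.149) and apoptosis and selection (0.163) lost the call with sc13062, and with sc816 only T cell receptor signalling and the negative regulators kept it. At a −log10 q of at least 5, T cell receptor signalling lost it with both antibodies (adjusted exact p = 0.0512 for sc13062 and 0.0568 for sc816), and the transcription factors with sc816 (0.364). At 50 kb the negative regulators lost it with sc816 (3 of 22, adjusted exact p = 0.149). The steroid-receptor list kept it there, with 7 of 24 genes (29.2%, against 4.35% of other genes, adjusted exact p = 0.000407).

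Markers of other cell types and the remaining lists did not pass with either antibody at 10 kb. With sc13062, a peak lay near 5 of 12 B cell, 3 of 13 myeloid, 2 of 12 thymic epithelial and 2 of 11 erythroid markers, with adjusted exact p from 0.28 to 1. It lay near 10 of 25 nuclear receptor and cofactor genes (adjusted exact p = 1), 14 of 31 effector and autoimmunity genes (0.841) and 10 of 15 histone genes (0.142). With sc816 the counts were 1 B cell marker (Blk, named after its value was seen), 1 effector gene (Pdcd1), 1 histone gene (H1f3) and 0 in the other 4 of these lists. Other settings gave calls that the main one did not. With sc13062, histone genes passed above other genes within 1 kb (10 of 15, adjusted exact p = 0.0184) and at a −log10 q of at least 5 (0.0484), and erythroid markers passed below them at the latter (0 of 11, 0.0447). With sc816, B cell (3 of 12, adjusted exact p = 0.041) and myeloid markers (3 of 13, 0.043) passed above other genes at 50 kb.

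**Figure D2:**
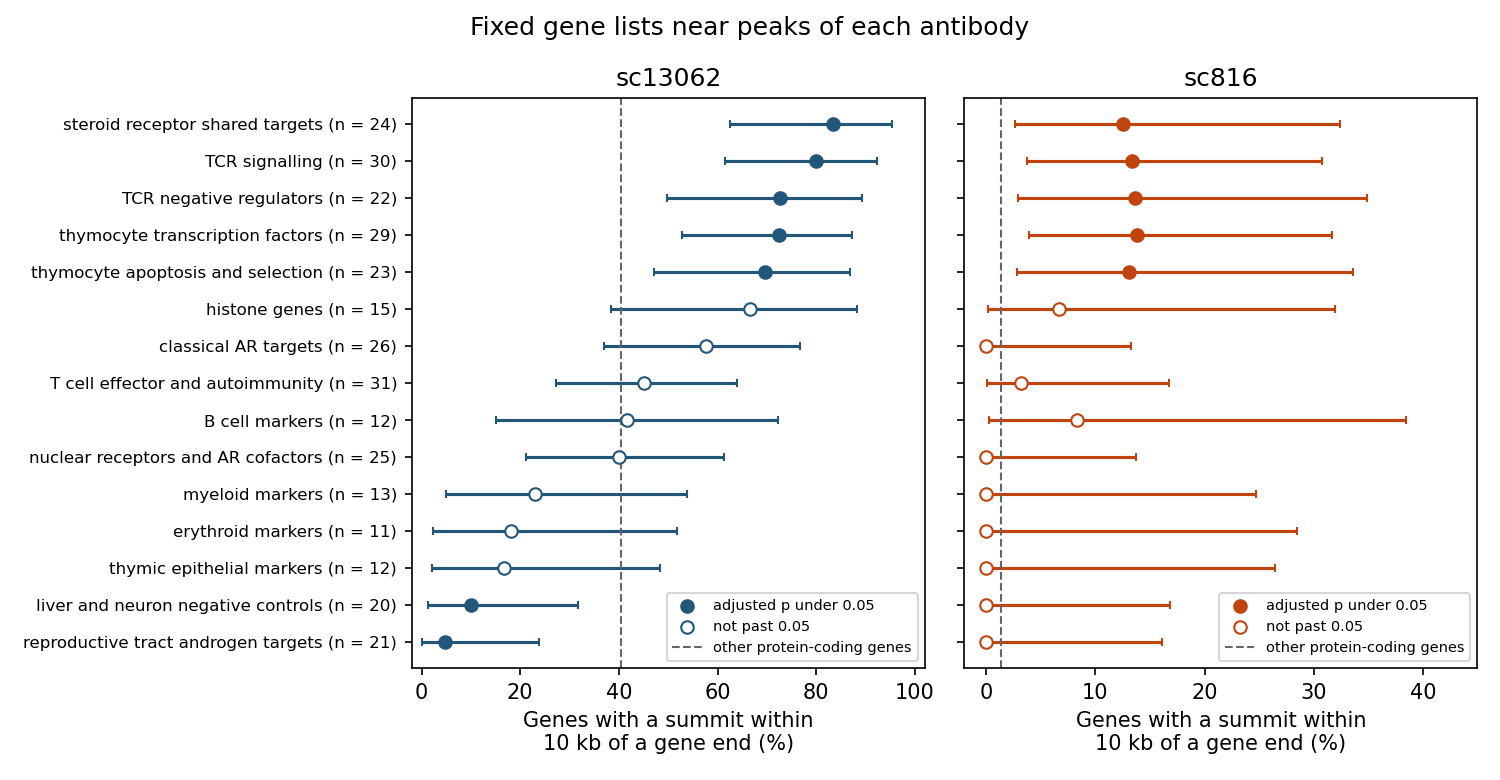
Percent of the genes of each fixed list with a peak summit within 10 kb of a gene end (horizontal axes, different scales) for sc13062 on the left and sc816 on the right; points are 1 library each, bars are exact 95% binomial intervals over genes, and filled points passed an adjusted Fisher exact p of 0.05. The dashed line marks other protein-coding genes, 40.5% for sc13062 and 1.37% for sc816, and 5 lists lie above it with an adjusted p under 0.05 in each panel.

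Among the 311 genes of the fixed lists, 159 had an sc13062 peak within 10 kb of a gene end, 20 an sc816 peak and 18 both. At 11 of these 18 a peak of one antibody overlapped a peak of the other. Overlapping peaks lay at Tnfaip3 and Sla2, which encode restraints on lymphocyte receptor signalling, with an sc816 fold enrichment of 9.61 and 6.94 and an overlapping sc13062 peak of 18.3 and 11.6. The same was true of Lat, the adaptor that links the T cell receptor to downstream signalling (10.7 with sc816, 6.93 with sc13062), Nr4a1, an orphan nuclear receptor induced by T cell receptor signals (7.32 and 5.95), Nfkbia, the NF-κB inhibitor (6.60 and 7.73), and Pdcd1, which encodes the inhibitory receptor PD-1 (6.36 and 7.04). The strongest sc13062 peaks within 10 kb of an end of Nr4a1 (34.4) and Nfkbia (26.4) lay at other positions. The sc816 peak 6505 bp from H1f3 is the shared peak inside H3c6 given above. At Egr1, Ccr7, Lck, Nfatc3, Cbfb and Cd69 both antibodies had a peak within 10 kb, but at different positions. The sc816 fold enrichment there ran from 5.27 (Nfatc3) to 13.9 (Cd69), and that of the strongest sc13062 peak from 8.53 (Cd69) to 44.3 (Egr1). Outside the rule for named genes, and chosen after their values were seen, Cd4, Cd2 and Klf9 were the other 3 genes near peaks of both antibodies, and Zbtb7b and Blk were near an sc816 peak alone.

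At Ptpn22, which encodes a phosphatase that restrains T cell receptor signalling (chromosome 3, 103856575 to 103912252), the sc816 library had 1 peak (103860212 to 103860337, fold enrichment 6.63). It lay inside the gene, 3681 bp from the nearer end, and overlapped an sc13062 peak (103859998 to 103860444, 11.4). The summits were at 103860256 and 103860283. Of the 5 sc13062 peaks inside Ptpn22 or within 10 kb of it, the strongest (15.6) lay 1880 bp beyond the other end of the gene, within the neighbouring gene Rsbn1. Ptpn1, another phosphatase gene, had 2 sc13062 peaks, both inside it (8.10 and 4.05), and 0 sc816 peaks inside it or within 10 kb. Per1, a circadian clock gene that glucocorticoids also induce, had 11 sc13062 peaks and 1 sc816 peak. The sc816 peak (chromosome 11, 69097057 to 69097228, 7.17) overlapped an sc13062 peak of 5.57. The strongest sc13062 peak near Per1 (17.2) lay 6506 bp outside it, inside the neighbouring gene Vamp2. Of the other steroid-responsive genes, Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, had an sc13062 peak of 36.4 inside the gene. Fkbp5, which encodes a steroid-receptor co-chaperone, had one of 16.8 at 90 bp from a gene end, and Zbtb16, a zinc-finger transcription factor gene, had one of 8.09 inside the gene. None of these 3 had an sc816 peak inside the gene or within 10 kb. Ar itself (chromosome X, 98148757 to 98323218) had 0 peaks inside it or within 10 kb in either list.

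**Figure D3:**
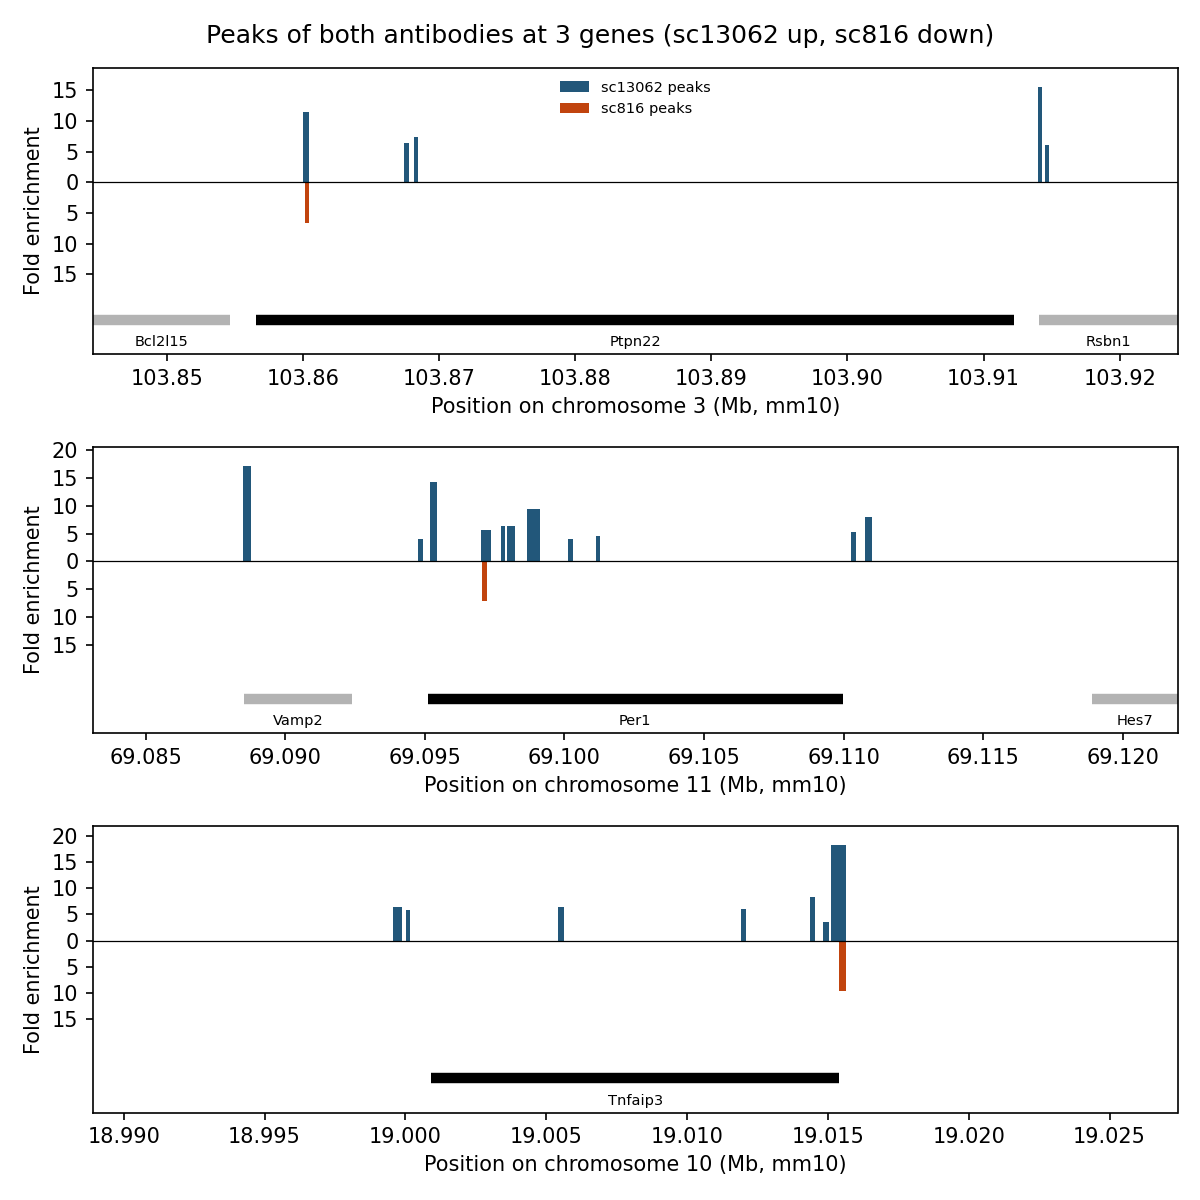
Peaks of sc13062 (upward bars) and sc816 (downward bars) around Ptpn22, Per1 and Tnfaip3, with position in Mb on mm10 on the horizontal axes and the authors' fold enrichment on the vertical axes; bars span the peak or a minimum drawing width, black lines are the named gene and grey lines neighbouring protein-coding genes. Each gene has 1 sc816 peak inside it or within 10 kb, with fold enrichments of 6.63, 7.17 and 9.61, and each overlaps an sc13062 peak.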

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

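The tests on the ranking, removed peaks, gene ends, ribosomal protein genes and the unplaced sequence were chosen after the result was seen, and the restriction to chromosomes 1 to 19 and X likewise. The share of peaks within 1 kb of a gene end stood out because it differed between antibodies raised against the same protein, by 48.5 percentage points, 64.7% for sc13062 and 16.2% for sc816 (two-sided Fisher exact p = 2.6e-109). The lists also had few peaks in common. If both antibodies had read 1 ranking of sites at different sensitivity, the sc816 peaks would overlap mainly the strongest sc13062 peaks. Of the top 10% of sc13062 peaks by fold enrichment, 2.10% overlapped an sc816 peak (23 of 1094, exact 95% interval 1.34 to 3.14%). The sc816 list had 519 peaks on these chromosomes, so most of these 1094 peaks could not be shared under any explanation. Still, 142 shared sc13062 peaks lay outside the top 10% and 23 in it. The share of 2.10% at the top was not told apart from the 1.44% of the others (142 of 9838, two-sided Fisher exact p = 0.0901). By −log10 q over all sequences, shared sc13062 peaks did stand higher, with medians of 10.1 against 7.44 (two-sided permutation p = 1e-05). The answer therefore depends on the measure of strength. Removal of sc816 peaks after calling could be set aside only for a part of the top peaks. Of the 1094, 578 (52.8%) were unshared and lay in stretches without missing sc816 numbers, where no removal is recorded. For unshared top peaks outside such stretches, removal was not tested and may account for the lack of overlap. Among the top sc13062 peaks that were shared or lay in stretches where sc816 peak numbers run on without a gap, 3.83% were shared (23 of 601, 2.44 to 5.69%). Ends of protein-coding genes that attract reads with any antibody do not account for all the sites in common. The sc816 peaks over 1 kb from a gene end still overlapped 375 times more often than at random (101 of 435, 23.2%, permutation p = 0.001). Gene ends may account for a part, since 62 of 84 sc816 peaks within 1 kb of one were shared (73.8%). Random positions do not mimic other places that may attract reads with any antibody, so attraction away from gene ends was not tested. Among what stays open is whether either antibody enriched sites without androgen receptor, for which no receptor-deficient or hormone-free cells were analysed here. The removal of 51.4% of sc816 and 5.68% of sc13062 peak numbers was not tested as a source of the difference in location. Library depth is unknown, and chance dips of an input used for both lists, a possible source of common sites, were not simulated. No biological explanation was tested.

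Genes of thymocyte function and steroid response lay near sc13062 peaks, and a candidate explanation is a preference for the ends of widely expressed genes whatever their function. Ribosomal protein genes had an sc13062 summit within 1 kb of a gene end in 74 of 83 cases (89.2%), 29.8 percentage points above the genes of the 5 lists that passed above other genes (76 of 128, 59.4%, two-sided Fisher exact p = 2.1e-06). So a peak at a gene end was not particular to the genes of those lists, as this explanation requires, and it stays open beside a regulation of these genes by the receptor, which was not tested. With sc816, summits lay within 1 kb at 2 of 83 ribosomal protein genes (2.41%) and 4 of 67 histone genes (5.97%), against 0.40% of all protein-coding genes. They lay at 0 of 39 proteasome, 0 of 49 respiratory complex I, 0 of 21 hnRNP and 0 of 11 SR splicing factor genes. These counts are too small to weigh the explanation for the lists that passed with sc816. Expression levels were not used here, so a list of expressed genes could not be set beside the thymocyte lists.

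Peaks on the unplaced sequence JH584304 lie outside the comparisons by chromosome and stood out by their number, 37 in the sc816 list and 32 in the sc13062 list. They made up 36 of the 207 shared sc816 peaks. Reads from many genomic copies piled onto 1 assembled copy are a candidate source. Such a pile would raise the local background along with the peak, and 100% of these peaks in each list had a fold enrichment below the median of the chromosome peaks of that list, with medians of 3.18 against 6.66 for sc816 and 3.05 against 7.04 for sc13062. The same range of positions in both lists was also required of this source. The peaks ran from 3832 to 114452 with sc816 and from 37208 to 114452 with sc13062, so that part was met at the upper end only. Copy number was not measured, and no biological explanation was tested.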

How the results depend on the processing

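The restrictions to chromosomes 1 to 19 and X, without the chromosome 4 cluster and with a background free of olfactory and vomeronasal receptor genes were chosen after the data were seen. The excess of shared peaks, stratified or not, and the gene-end share above random kept their direction and side of the threshold under every alternative run, with overlap ratios from 3.19 to 171 unstratified and from 3.08 to 44.8 stratified. Peak counts moved by over 1.5 times at a −log10 q of at least 10 (3810 for sc13062, 139 for sc816) and at 5 (362 for sc816). The percent of sc816 peaks shared, 36.2%, left its interval with reciprocal overlap of 50% (21.2%), summits within 100 bp (28.0%), a fold enrichment of at least 5 (28.1%), the shortened sc13062 list (2.10%), chromosomes 1 to 19 and X or without unplaced sequences and wide peaks (31.4% for each), and without both the chromosome 4 cluster and the unplaced sequences (30.0%). The fold difference of shared peaks, -0.12 on the log2 scale in the sc13062 list, turned to 0.047 on chromosomes 1 to 19 and X, where weak shared peaks of the unplaced sequences are left out, and to 2.65 in units of −log10 q. In the sc816 list it went from 0 to 0.098 and 2.78, past the threshold.

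The number of lists above other genes with sc816, 5, was 3 at a −log10 q of at least 5 and 2 within 1 kb. With sc13062 it was 5 and 4, histone genes included, which were not among the 5 of the main setting. Of 2 lists below other genes with sc13062, 1 passed at 50 kb, where liver and neuron genes lost the call (-22.8 points, adjusted exact p = 0.1). Among the single lists, 18 alternatives turned the sign, and 16 of them started from a difference that had not passed the test. In percentage points with sc13062, B cell markers went from 1.19 to -10.4 at a −log10 q of at least 5, -0.41 with the gene body, -30.1 within 1 kb and -1.67 with the reduced background, and nuclear receptors and cofactors from -0.47 to 0.64, 5.93 and 9.97 under the first 3 of these. With sc816, values within 1 kb fell to -0.40 for B cell markers, effector genes, histone genes, apoptosis and selection, and transcription factors, where no member had a peak. Histone genes gave -0.85 at a −log10 q of at least 5. Of the 7 lists with no sc816 peak at 10 kb, 4 turned positive in a wider window: classical androgen targets to 1.86 with the gene body and 3.32 at 50 kb, nuclear receptors to 2.01 with the gene body (but -4.38 at 50 kb), liver and neuron genes to 0.62 and myeloid markers to 18.7 at 50 kb. At 50 kb with sc816, myeloid markers and B cell markers (20.6) passed the adjusted exact test (p = 0.043 and 0.041) and the negative regulators did not (0.149). Other causes were not tested. Alternatives on transcript starts, pileup and response elements were not run, and no paired or leave-one-out analysis was possible because each antibody has 1 library. Unknown depth limits every count of peaks.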

Other observations

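The groupings by gene family, region and chromosome were chosen after the data were seen, as was the matching of intervals by length. With sc13062, gene families that every dividing cell uses had peaks at their ends more often than the 30.0% of all protein-coding genes. A summit lay within 1 kb for 10 of 11 SR splicing factor genes, 17 of 21 hnRNP genes, 30 of 49 genes of respiratory complex I and 22 of 39 proteasome genes. At the other extreme were 1 of 1110 olfactory receptor, 1 of 355 vomeronasal receptor and 0 of 53 keratin genes. Histone genes stood out in strength: 39 of 67 had a peak, and the median of the strongest fold enrichment per gene was 29.8, against 8.27 for other genes with a peak (log2 difference 1.85, two-sided permutation p = 1e-05, the smallest possible). X-linked genes had an sc13062 peak at an end less often than autosomal genes, 12.4% against 30.9% (two-sided Fisher exact p = 1.23e-39).

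The sc13062 peaks also formed groups, joined here when up to 12.5 kb apart. The group with the most peaks held 23 at Hip1r and Vps37b (chromosome 5, 124001818 to 124032348), followed by groups of 21 in a histone gene cluster on chromosome 13, 18 at Coro1c and Selplg, the latter encoding the P-selectin ligand PSGL-1, and 16 across Cd3d, Cd3e and Cd3g, which encode CD3 subunits of the T cell receptor complex (chromosome 9, 44965483 to 45016265). Next came 14 at Dnajb13 and Ucp2, and groups of 13 at a second histone cluster on chromosome 13, at Itk and Cyfip2, at Cbx3, at Atp5d and along the interferon zeta-like genes described next. Of these groups, the larger histone cluster held 2 peaks that overlapped an sc816 peak, the interferon zeta-like genes 11, and the others 0. On chromosomes 1 to 19 and X the sc816 list had 1 group of 3 or more peaks, with 16 peaks along 13 interferon zeta-like genes on chromosome 4 (88760109 to 88806362), 12 of which overlapped sc13062 peaks. Their median fold enrichment was 7.20 with sc816, and 6.46 for the 14 sc13062 peaks there. Sharing of reads between these related genes was not tested.

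Numbers are missing from the peak names of both lists, and a candidate explanation is the removal of peaks at tRNA genes and similar repeats. Intervals between neighbouring peaks with missing numbers held 224 of the 367 tRNA genes lying between sc816 peaks and 67 of 394 for sc13062, against 94.3 ± 44.2 and 11.4 ± 12.5 in random intervals of any length (permutation p = 0.004 and 0.005). Such intervals were also longer. Against intervals of like length the random counts were 155 ± 45.6 and 26.1 ± 18.9 (permutation p = 0.093 and 0.047, adjusted 0.0929 for both), so removal at tRNA genes and plain interval length cannot be told apart with these lists.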
